A study of Danio rerio with 6 samples.

How the data were processed

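Whole zebrafish (Danio rerio) embryos were collected at 4 days post fertilization after injection of either a control morpholino or a splice-blocking morpholino against glut12, the gene listed in the files as slc2a12. Each of the 6 libraries was made from total RNA of 10 pooled embryos, with 3 libraries per group, per the labels. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the pools of a group came from separate clutches, so p-values measure the spread between these pools, which may be partly technical.

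The deposited files give 1 value for each of 31452 Ensembl genes, with a chromosome and a symbol. The genome build was Zv9, per the submitters' processing notes. The aligner, the counting program and the use of strand are not given in the sources used here. The deposited values are a score with no fixed range: read counts per gene that had been divided by a size factor for the library and rounded to whole numbers. This reading comes from the values. Rounding of reads times a constant leaves some low whole numbers unused or makes some stand for more than 1 read count. Step sizes were searched for the best fit to how often each low whole number was used. The search gave the worth of 1 read as 1.56 in control 1, 0.986 in control 2, 1.08 in control 3, 0.708 in morphant 1, 0.721 in morphant 2 and 1.11 in morphant 3. The fitted step of control 1 leaves 36 of the first 100 whole numbers unused, and those of morphants 1 and 2 use 41 and 39 of them doubly. These counts follow from the steps and were not observed separately. In control 1, 99.8% of the positive values below 400 lay at numbers its step allows. Rounding prevents recovery of exact reads, and no test of raw reads was run. The value totals divided by these steps estimate depths of 7550000, 11610000 and 10250000 reads in controls 1, 2 and 3 and of 15170000, 14430000 and 9490000 reads in morphants 1, 2 and 3. Low genes are therefore measured least precisely in control 1.

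The test planned for raw counts did not suit the unit, and the planned fallback for normalized values was used. Genes with a value of at least 1 in at least 3 libraries were kept (26082 genes). Values were transformed as log2(value + 1) and compared between groups with limma 3.58.1 in R 4.3.3, with group as the single term, a mean-variance trend in the empirical Bayes step and two-sided p-values under Benjamini-Hochberg adjustment at 0.05. The trend was chosen after the data were seen, because calls without it were dominated by genes at 0 in one group and 1 in the other. Fold changes are on the log2(value + 1) scale, which understates the change of low genes, and are given as morphant minus control with the standard error (SE). No further scaling was applied to the deposited values.

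Gene lists of 41 pathways, tissues and cell types, the named-gene rule and the tests were fixed before the data were examined. Exceptions are the trend, the settings named as chosen later and the tests of observed patterns that close the report. Of 1319 list entries, 1233 were found, by the files' symbols or by current symbols paired with the gene IDs. Each list was compared with all other tested genes by camera in limma, with a preset correlation of 0.01 and adjustment over the 41 lists. It was tested again with a correlation estimated from the data, and by fry, which asks whether the members of a list move on balance one way. For members, the number past an adjusted p of 0.05 is given over all genes and adjusted over the list alone. Named genes were slc2a12, up to 10 called genes with a symbol in each direction with the largest change, at least 5 per 1000000 of the library total in the higher group and no overlap between groups, up to 4 members of each list with the lowest adjusted p, and ins, gcga, pck1, hk1, hk2, nppa, nppb, myl7, vmhc, myh6, cdkn1a and mdm2. Some results covered by this rule are not reported here.

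The alternatives were other scalings of the libraries, other filters on low values, a pseudocount of 0.1, voom in limma on estimated reads, a test against a 1.5-fold change, the replicate number as a block and each library left out in turn. Chosen after the data were seen were limma without the trend, a robust empirical Bayes step and library weights estimated by limma. The fit and the list test were tested on simulated data, in 5 runs of reads drawn for the 26082 tested genes at the estimated depths. In each run 200 genes were changed, none of them from the genes with the lowest means. The fit recovered 17.3% of those changed 1.5-fold, 61.2% of those changed 2-fold and 93.6% of those changed 4-fold. These shares do not hold for low genes. In these runs 27 of 606 calls were of unchanged genes, and a list shifted by -0.3 on the log2 scale was called in all 5 runs. Other lists were called 3 times in all over these runs. The simulated genes varied independently of each other. Apart from depth, no simulated library stood apart as control 1 did. Figures were drawn with matplotlib.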

Results

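RNA was sequenced from whole zebrafish embryos at 4 days post fertilization. The 6 libraries, each from 10 pooled embryos, fall into 2 groups: 3 from embryos injected with a control morpholino and 3 from embryos injected with a morpholino that blocks splicing of glut12 (morphants). A morpholino is an antisense oligomer that binds a transcript. The glut12 gene, listed as slc2a12, encodes a sugar transporter of the GLUT family. Totals of the normalised read counts lay between 10397713 (morphant 2) and 11762915 (control 1), and estimated depths between 7550000 (control 1) and 15170000 reads (morphant 1). Control 1 stood apart from the other controls. Over 15942 genes with a mean of at least 50, the log2 values of control 1 correlated with those of controls 2 and 3 at r = 0.961 and r = 0.955, against r = 0.987 between controls 2 and 3, where genes are not independent replicates. The first principal component held 64.5% of the variance and placed control 1 at -58.6. Controls 2 and 3 lay at -5.12 and -0.47 on it, and morphants 1, 2 and 3 at 17.0, 24.1 and 23.1. It thus also separated the groups, and the deviation of control 1 and the group difference share this component.

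**Figure D1:**
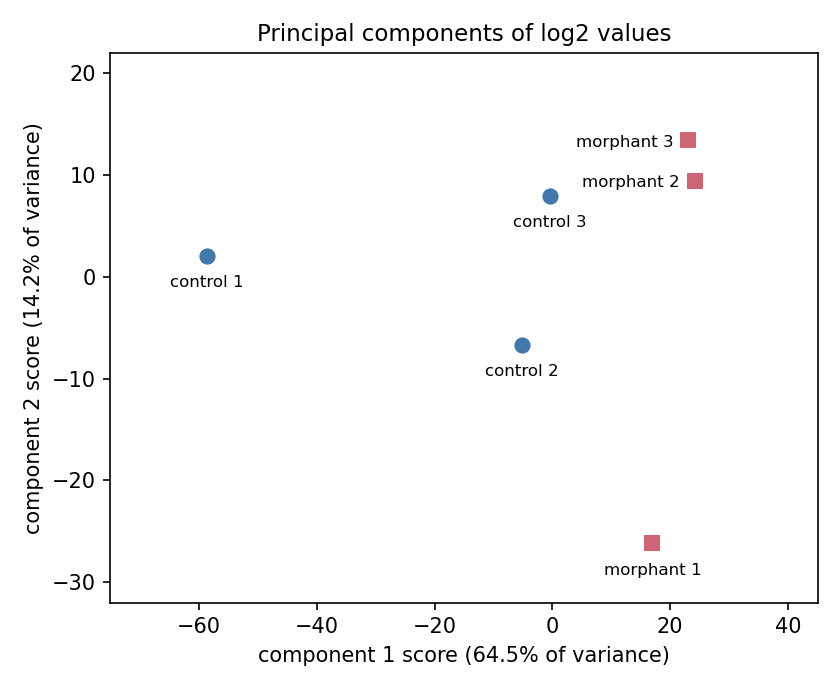
Scores of the 6 libraries on the first 2 principal components of log2 values (axes give scores, with the percent of variance each component holds); circles are controls and squares are morphants. Control 1 lies at -58.6 on the first component, where all morphants lie above all controls, and morphant 1 lies at -26.2 on the second.

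The comparison asked which transcripts differed in embryos in which glut12 splicing was blocked, among them those of the heart and of glucose metabolism, which the study's title names. The targeted gene, slc2a12 (chromosome 23, Zv9), had normalised read counts of 160, 145 and 143 in the controls and 98, 97 and 90 in the morphants. Its log2 fold change was -0.65 ± 0.13 (SE, n = 3 per group), 36.1% lower on that scale and lower in all 3 morphants, with an unadjusted p of 0.00092 that did not pass adjustment over all genes (adjusted p = 0.158, limma with Benjamini-Hochberg). A splice-blocking morpholino changes how a transcript is joined and need not lower its read count. With library weights estimated by limma, slc2a12 passed (adjusted p = 0.0467, range over the alternatives 0.0467 to 1).

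In morphants 6 genes rose and 0 fell among the 26082 genes tested. The F-box-family gene zgc:114174 (chromosome 23), named fbxo44.7 in the current gene table, rose from 79.7 ± 5.03 to 1989 ± 627 (SD, n = 3 per group), a log2 fold change of 4.57 ± 0.23 (adjusted p = 0.00058, limma with Benjamini-Hochberg). The gene si:dkeyp-87e3.1 (chromosome 8) was at 2, 6 and 2 in the controls and at 258, 312 and 152 in the morphants (log2 fold change 5.86 ± 0.41, limma adjusted p = 0.0052). The type I TGF-beta receptor gene tgfbr1b (chromosome 24) rose from 14 ± 6.08 to 132 ± 32.7, and a gene with a clone-based symbol, ENSDARG00000093349 (chromosome 9), from 253 ± 25.03 to 1250.3 ± 367. The epithelial calcium channel gene trpv6, used by ionocytes of the skin, rose from 356 ± 27.9 to 865 ± 134, and rcc1, which encodes the guanine nucleotide exchange factor for Ran, from 230 ± 14.5 to 543 ± 86.0. Both lie on chromosome 16. Their log2 fold changes were 3.19 ± 0.32 for tgfbr1b, 2.25 ± 0.21 for ENSDARG00000093349, 1.27 ± 0.13 for trpv6 and 1.23 ± 0.13 for rcc1 (limma adjusted p = 0.039, 0.036, 0.039 and 0.048). All 3 morphants lay above all 3 controls for each of the 6 genes. Members of gene families such as zgc:114174 can share reads with close copies, and its value is uncertain to that degree.

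At an unadjusted p of 0.05, limma gave 2346 higher and 1808 lower genes, 4154 in all where 1304 are expected by chance, with 1173 and 1109 without morphant 2 and 1345 and 1214 without morphant 3. With libraries scaled to equal totals the split was 3793 to 795, as the median of all genes then moved by 0.11 on the log2 scale. Genes do not vary independently, and other groupings of the 6 libraries into 3 and 3 gave 432 to 2126 genes in all at an unadjusted limma p of 0.05. The groups did not overlap for 5690 genes (21.8%), where chance gives 10%. The smallest adjusted p of a lower gene was 0.061 in limma, and voom on estimated reads called 21 higher and 20 lower genes. With 1 library left out limma called 3 higher genes without control 1, 2 without control 2, 1 without control 3, 3 without morphant 1, 1 without morphant 2 and 4 without morphant 3, and 1, 0, 0, 2, 0 and 1 lower genes in that order. Of the 6 genes above, 2, 2, 1, 3, 1 and 4 kept their calls in these fits. The call of zgc:114174 held in all 18 alternatives and that of si:dkeyp-87e3.1 in 16, the exceptions being without control 3 (adjusted p = 0.1) and without morphant 2 (adjusted p = 0.079). The other 4 genes lost their calls without control 1 (limma adjusted p of 0.072 to 0.081).

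**Figure D2:**
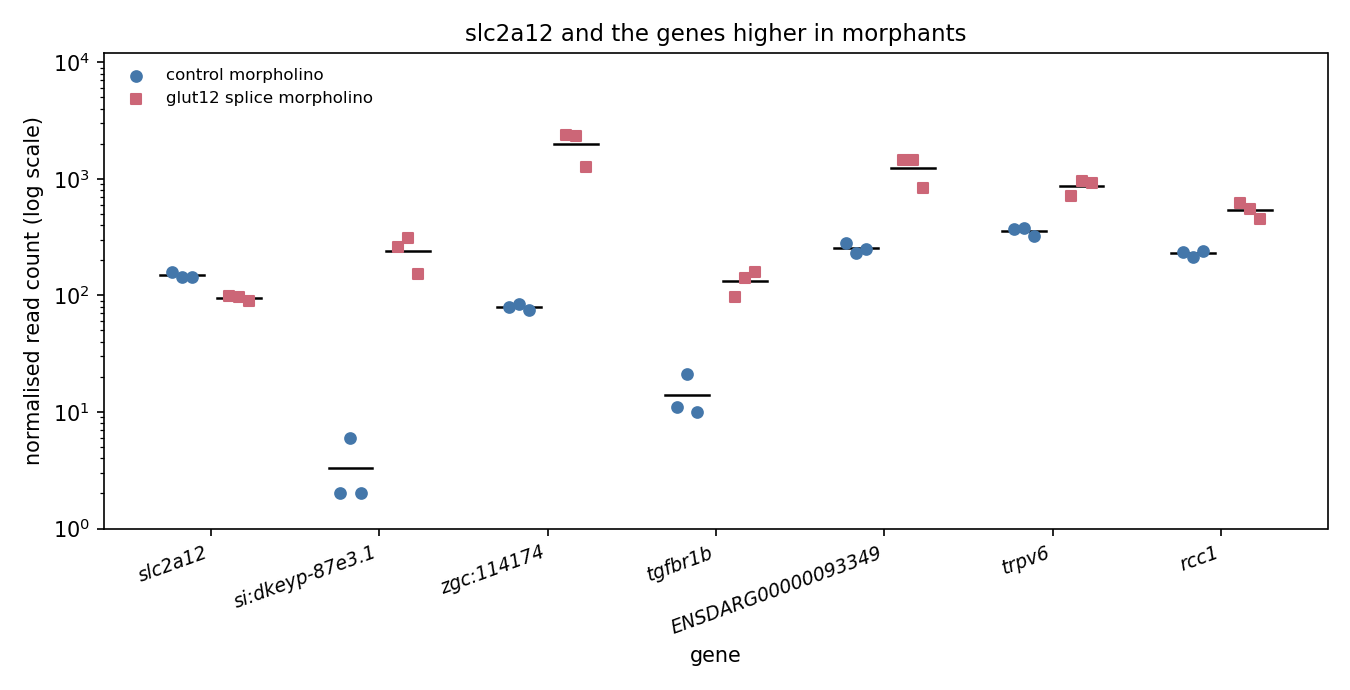
Normalised read counts of slc2a12 and of the 6 genes called higher in morphants, on a log axis, with 1 point per library (circles for controls, squares for morphants) and a line at each group mean. For slc2a12 the morphants lie at 90 to 98, below the controls at 143 to 160, and for zgc:114174 they lie at 1266 to 2385, above the controls at 75 to 85.

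Of the 41 gene lists, camera called 13 lower and 3 higher in morphants, and 0 of the 41 with an estimated correlation or by fry. Genes of protein synthesis and of energy metabolism were among the lists called lower. Counts of members adjusted over the list alone changed with the libraries used, and those for 1 library left out are given in the order of controls 1, 2 and 3 and morphants 1, 2 and 3. Of 76 cytosolic ribosomal protein genes, all 76 had a negative log2 fold change, with a median of -0.26 (camera adjusted p = 4.2e-19; adjusted p = 0.571 with an estimated correlation). With all 6 libraries 0 members were lower over all genes and 0 adjusted over the list alone, the latter count being 49 without control 3 and 34 without morphant 1. The gene rps2 was at 19793 ± 2884 in controls and 14548 ± 736 in morphants (SD, n = 3 per group). The nuclear genes of oxidative phosphorylation had a median of -0.23, with 66 of 69 negative (camera adjusted p = 6.9e-14; adjusted p = 0.571 with an estimated correlation), and again 0 members passed over all genes or adjusted over the list alone. Among them were the complex I subunit gene ndufs5 at 596 ± 91.9 and 400 ± 41.0, and cox5aa of complex IV at 7610 ± 1083 and 5580 ± 279. The tricarboxylic acid cycle list, which includes pyruvate dehydrogenase, had a median of -0.20, with all 27 genes negative (camera adjusted p = 6.4e-07; adjusted p = 0.571 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. Its members included pdhb at 2094 ± 225 and 1619 ± 17.3. The 13 mitochondrially encoded genes had a median of -0.21 (camera adjusted p = 5.9e-05; adjusted p = 0.571 with an estimated correlation). Of these, mt-atp8 passed adjusted over the list alone (13164 ± 753 and 10380.7 ± 162), 1 gene against 0 over all genes, and the count over the list alone was 0 without control 1 or any 1 morphant.

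Glycolysis genes had a median of -0.19, with 28 of 32 negative (camera adjusted p = 1.8e-07; adjusted p = 0.571 with an estimated correlation). In this list 5 genes were lower adjusted over the list alone (5, 7, 1, 0, 0 and 0 with 1 library left out) and 0 over all genes. Among them were the muscle phosphofructokinase gene pfkma (1620 ± 152 and 1208 ± 46.9), the aldolase gene aldoab (6265 ± 571 and 4488 ± 237), pgam2 (1425 ± 177 and 1018 ± 53.2) and the pyruvate kinase gene pkmb (7929 ± 1085 and 5766 ± 302). The fifth, aldoaa, was chosen after its values were seen. The libraries did not contribute evenly. In control 1 the median member lay above that in controls 2 and 3 by 0.27 for ribosomal proteins, 0.31 for oxidative phosphorylation, 0.26 for the tricarboxylic acid cycle, 0.29 for mitochondrially encoded genes and 0.18 for glycolysis. Without control 1 the medians were -0.17, -0.12, -0.10, -0.11 and -0.14 in that order, and camera still called all 5 lists. Scaling the libraries to equal totals, which moved the median of all genes by 0.11, gave medians of -0.15, -0.12, -0.09, -0.10 and -0.08 in that order, and all 16 list calls were kept. With library weights the tricarboxylic acid cycle median was -0.13.

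Structural and tissue marker genes formed most of the other lists called lower. Of 46 lens genes, mostly crystallins that fill the lens fibres, 38 were negative and the median was -0.33 (camera adjusted p = 1.5e-10; adjusted p = 0.571 with an estimated correlation). Of these 17 were lower adjusted over the list alone (13, 11, 22, 0, 13 and 0 with 1 library left out) and 0 over all genes. Examples were crybb1 (11926 ± 1569 and 8351 ± 664) and crygm2d5 (4450.3 ± 575 and 3064 ± 141), the latter one of a family of close copies among which reads may be shared. For cartilage, bone and fibrillar collagen the median was -0.26, with 32 of 35 negative (camera adjusted p = 4.7e-09; adjusted p = 0.571 with an estimated correlation). There 12 genes were lower adjusted over the list alone (10, 8, 8, 15, 6 and 6 with 1 library left out) against 0 over all genes. The collagen genes col1a1a (44412 ± 4697 and 27858 ± 2072), col1a2 (21392 ± 1958 and 13903 ± 891) and col9a1 (3272 ± 309 and 1658 ± 420) and the matrix protein gene sparc (13343 ± 933 and 9370 ± 375) were among the 12. Their log2 fold changes were -0.67 ± 0.12, -0.62 ± 0.10, -1.01 ± 0.17 and -0.51 ± 0.09 (SE).

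Skeletal muscle genes had a median of -0.21, with 30 of 39 negative (camera adjusted p = 3.9e-05; adjusted p = 0.571 with an estimated correlation). Of the members 8 were lower adjusted over the list alone (6, 3, 8, 16, 0 and 0 with 1 library left out) against 0 over all genes. They included acta1b (28098 ± 2130 and 18447 ± 2564), the fast myosin light chain gene mylz3 (54682 ± 4735 and 38231 ± 1697) and the calcium pump gene atp2a1 (84889 ± 2922 and 60745 ± 4767). Skin, periderm and ionocyte genes had a median of -0.21 (camera adjusted p = 3.9e-05; adjusted p = 0.571 with an estimated correlation). There 5 genes were lower (5, 2, 5, 13, 0 and 0 with 1 library left out) and 1 higher (2 without control 3) adjusted over the list alone, and 1 higher over all genes. The higher gene was trpv6, and the lower ones were the keratin gene krt5 (29992 ± 2026 and 20585 ± 2017), anxa1c (486 ± 31.9 and 319 ± 54.2) and pvalb8 (723 ± 82.3 and 523 ± 21.5), with cyt1 and epcam named after their values were seen. Of the myelin and glia genes 5 were lower (5, 3, 5, 7, 0 and 0 with 1 library left out) and 1 higher (0 without control 1, morphant 2 or morphant 3) adjusted over the list alone and 0 over all genes. Their median was -0.20 (camera adjusted p = 0.0093; adjusted p = 0.571 with an estimated correlation). The astroglial filament gene gfap (3397 ± 132 and 2625 ± 178), fabp7b (35.3 ± 6.35 and 11.7 ± 5.03), cldnk (178 ± 20.8 and 122 ± 8.50) and slc1a2b (8654 ± 168 and 7088 ± 236) were lower. The fifth lower gene, glula, and the higher one, the water channel gene aqp4 (4 ± 2 and 16 ± 7), were named after their values were seen. Relative to controls 2 and 3, the median member in control 1 lay higher by 0.27 for lens, 0.08 for cartilage, 0.08 for muscle, 0.06 for skin and 0.06 for glia. Without morphant 1 the glial median was -0.13. With equal library totals the medians were -0.22 for lens, -0.15 for cartilage, -0.09 for muscle, -0.10 for skin and -0.09 for glia.

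Photoreceptor, exocrine pancreas and hatching gland genes made up the other 3 lists called lower. For photoreceptors the median was -0.27, with 32 of 42 genes negative (camera adjusted p = 3.9e-05; adjusted p = 0.676 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone (1 without control 2). The cone transducin gene gngt2b was at 4681 ± 464 in controls and 3229 ± 644 in morphants, and the median of the list was -0.07 without morphant 1 (camera adjusted p = 0.0467), -0.10 with library weights and -0.16 with equal library totals. Exocrine pancreas genes, which encode digestive enzymes, had a median of -0.54 (camera adjusted p = 0.005; adjusted p = 0.856 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. The lipase gene cel.1 was at 1268, 908 and 860 in the controls and at 450, 711 and 991 in the morphants. That list's median was -0.35 without control 1 (camera adjusted p = 0.153), 0.01 without morphant 1 (camera adjusted p = 0.948) and -0.86 without morphant 3, and with library weights it was -0.13 and not called (camera adjusted p = 0.526). In control 1 the median exocrine gene lay 0.64 above controls 2 and 3, and the median photoreceptor gene 0.19 above them. The 7 hatching gland genes had a median of -0.24 (camera adjusted p = 0.027; adjusted p = 0.571 with an estimated correlation). Of these 2 were lower adjusted over the list alone (1, 0, 0, 0, 2 and 2 with 1 library left out) and 0 over all genes, the hatching enzyme genes he1a (38.3 ± 18.9 and 12 ± 6.08) and he1b (22 ± 7.21 and 4.67 ± 4.04). This call was lost without control 1 (camera adjusted p = 0.085) and without control 3 (camera adjusted p = 0.077), and without morphant 3 the median was -0.38. It was also lost with no filter on low values (median -0.17, camera adjusted p = 0.056), with a stricter one (median -0.10, camera adjusted p = 0.397) and with library weights (camera adjusted p = 0.061). Equal library totals gave a median of -0.13.

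**Figure D3:**
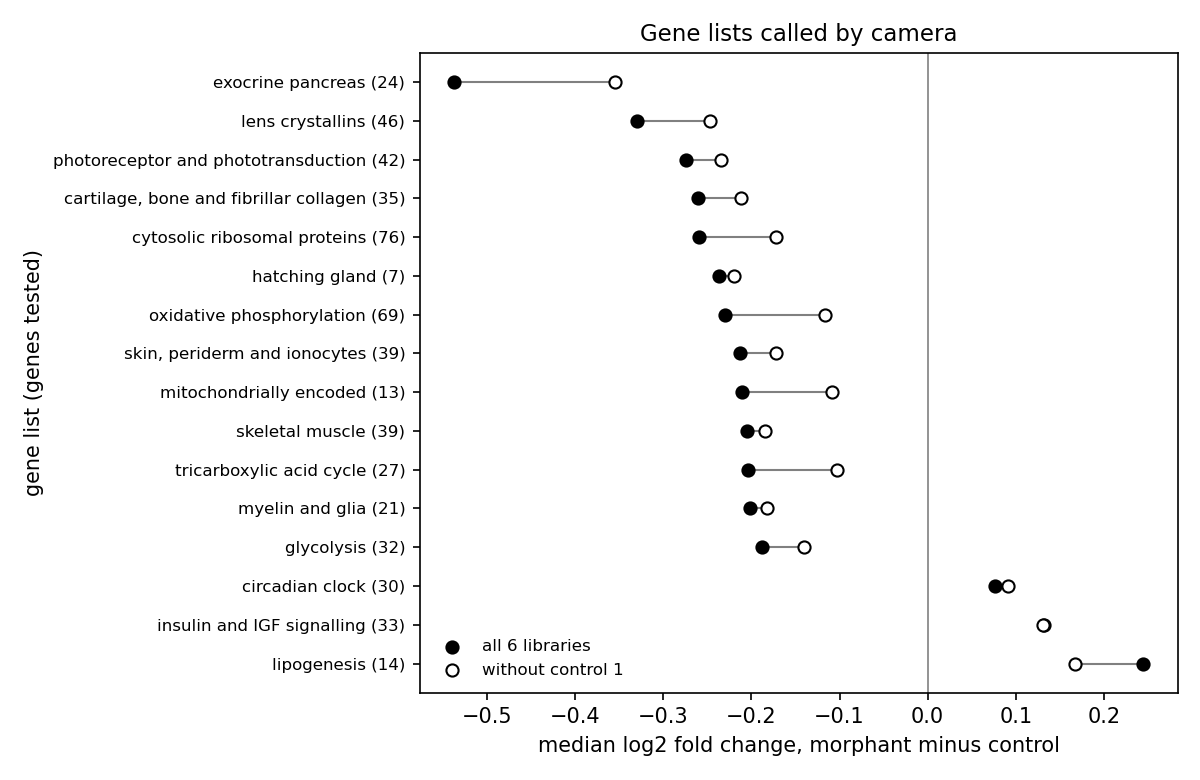
Median log2 fold change (morphant minus control, horizontal axis) of the 16 gene lists called by camera, with the number of tested genes in brackets; filled points use all 6 libraries and open points leave out control 1. The median is closer to 0 without control 1 for 15 of the 16 lists, among them oxidative phosphorylation at -0.23 and -0.12.

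Camera called 3 lists higher in morphants. All 14 lipogenesis genes had positive log2 fold changes, with a median of 0.24 (camera adjusted p = 0.0054; adjusted p = 0.571 with an estimated correlation). Among them 0 members passed over all genes or adjusted over the list alone (2 without control 3 and 3 without morphant 1). Acetyl-CoA carboxylase acacb was at 507 ± 65.3 in controls and 684 ± 69.5 in morphants (SD, n = 3 per group), lpin1 at 317 ± 63.1 and 462 ± 75.4 and the elongase gene elovl5 at 83 ± 21.9 and 123 ± 2.52. Circadian clock genes had a median of 0.08, with 22 of 30 positive (camera adjusted p = 0.01; adjusted p = 0.571 with an estimated correlation). Of the clock genes 3 were higher adjusted over the list alone (3, 4, 3, 7, 3 and 1 with 1 library left out) against 0 over all genes. These were per3 (62 ± 25.2 and 287 ± 112), rorcb (8.67 ± 3.51 and 33.7 ± 5.86) and arntl2 (65 ± 20.8 and 147 ± 10.6). The insulin and IGF signalling list had a median of 0.13, with 21 of 33 positive (camera adjusted p = 0.037; adjusted p = 0.571 with an estimated correlation). In it 2 genes were higher adjusted over the list alone (4, 0, 3, 2, 0 and 0 with 1 library left out) against 0 over all genes. With all 6 libraries these were the insulin receptor gene insrb (146 ± 34 and 310.0 ± 58.3) and igf1ra (100 ± 30.5 and 223 ± 54.3). In control 1 the median member of these lists lay below that of controls 2 and 3, by -0.19 for lipogenesis, -0.11 for the clock and -0.09 for insulin and IGF signalling. Without morphant 1 the medians of lipogenesis and the clock were 0.38 and 0.17. With equal library totals those of the clock and of insulin and IGF signalling were 0.19 and 0.24, and with library weights that of the clock was 0.16. Without morphant 2 the calls of the clock (camera adjusted p = 0.059) and of insulin and IGF signalling (camera adjusted p = 0.1) were lost, and without control 2 that of insulin and IGF signalling (camera adjusted p = 0.151).

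The glucose transporter, gluconeogenesis, endocrine pancreas and both cardiac lists were not called by camera with all 6 libraries, unlike glycolysis and insulin and IGF signalling. The mixed test of fry, open to changes in either direction, called gluconeogenesis, endocrine pancreas and the cardiac contractile list (mixed fry adjusted p = 0.028, 0.015 and 0.025). The glucose transporter list did not include the targeted slc2a12. Of its 18 genes 9 were positive and 9 negative (camera adjusted p = 0.833), with 0 passing over all genes or adjusted over the list alone (2 lower without morphant 1). The lowest adjusted p in this list was that of slc2a5 (66 ± 11.4 and 38.3 ± 15.04). The gluconeogenesis list had a median of -0.09 (camera adjusted p = 0.112), and camera called it lower without control 2 (median -0.19, adjusted p = 0.028) and without morphant 3 (median -0.14, adjusted p = 0.016). Without control 1 its median was above 0, at 0.04 (camera adjusted p = 0.697). In it 2 genes were lower and 0 higher adjusted over the list alone (1 higher without control 1) and 0 over all genes, the fructose-bisphosphatase genes fbp2 (1354 ± 106 and 888 ± 87.3) and fbp1a (408 ± 12.2 and 288 ± 19.5). The gluconeogenic enzyme gene pck1 was at 1966 ± 402 and 1385 ± 312, a log2 fold change of -0.51 ± 0.19 that did not pass (limma adjusted p = 0.264). The hexokinase genes hk1 (-0.18 ± 0.08, and -0.07 with equal library totals) and hk2 (-0.05 ± 0.15, and 0.063 with equal library totals) did not pass either. In the endocrine pancreas list (camera adjusted p = 0.278) the somatostatin gene sst3 was lower adjusted over the list alone (175 ± 12.5 and 103 ± 10.97), 1 gene (0 without morphant 2) against 0 over all genes. A member was higher without control 3. Insulin, ins, was at 198, 152 and 164 in the controls and 138, 127 and 140 in the morphants (-0.33 ± 0.14, and -0.22 with equal library totals, limma adjusted p = 0.3). Glucagon, gcga, had a log2 fold change of 0.27 ± 0.21 (limma adjusted p = 0.569), or 0.48 without morphant 1 and 0.16 without morphant 2 or morphant 3 and 0.44 with library weights.

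The cardiac contractile and structural list gave a camera adjusted p of 0.833 and the list of cardiac stress and transcription factors one of 0.987. In the contractile list actc1a (2732 ± 211 and 1772 ± 160) and the myosin-binding protein gene mybpc3 (1594 ± 84.8 and 1220 ± 60.9) were lower adjusted over the list alone, 2 genes (2, 3, 2, 2, 1 and 1 with 1 library left out) against 0 over all genes. Without control 3 another 2 were higher. In the stress list 0 members passed over all genes or adjusted over the list alone. The natriuretic peptide gene nppa, a marker of cardiac load, was at 115, 90 and 119 in the controls and 133, 123 and 124 in the morphants (0.24 ± 0.15, and 0.11 without control 2, limma adjusted p = 0.469). The nppb row, listed as BX323876.3, was at 8, 8 and 5 and at 36, 6 and 8 (limma adjusted p = 0.571). Log2 fold changes of the cardiac myosin genes were -0.49 ± 0.15 for myl7, 0.27 ± 0.12 for vmhc and 0.60 ± 0.24 for myh6 (limma adjusted p = 0.218, 0.324 and 0.283), and without control 1 those of vmhc and myh6 were 0.15 and 0.36. With library weights that of vmhc was 0.13. Log2 fold changes of the cell cycle inhibitor gene cdkn1a and of the ubiquitin ligase gene mdm2 were 0.10 ± 0.18 and 0.34 ± 0.14 (limma adjusted p = 0.803 and 0.31), in ranges of -0.05 to 0.23 and 0.21 to 0.43 with 1 library left out. For cdkn1a it was 0.22 with equal library totals and 0.20 with library weights. Median, mean and test had the same sign in all 16 called lists and differed in sign in 12 of the 25 others, the contractile, glucose transporter and endocrine lists among them.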

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

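The settings chosen after the data were seen were limma without the mean-variance trend, with a robust empirical Bayes step and with estimated library weights. Main counts were 6 genes higher and 0 lower, with 16 of 41 lists called. Higher and lower genes numbered 10 and 1 with equal library totals, 10 and 2 with a stricter filter (5 per 1000000 of the library total in 3 libraries), 21 and 20 with voom, 24 and 6 without the trend, 32 and 19 with the robust step and 217 and 112 with library weights. Lower genes numbered 1 with upper quartile scaling and 1 without a filter. Higher genes numbered 2 in each of the replicate block, the test against a 1.5-fold change and a pseudocount of 0.1. Leaving out 1 library gave 1 to 4 higher genes, 0 to 2 lower genes and 14 to 19 lists. All 6 main calls were kept under every scaling, both filters, voom, the robust step and library weights, and 2 of them under the block, the 1.5-fold test, the pseudocount of 0.1 and limma without the trend. Control 1 had the lowest library weight, 0.316. The causes of these shifts were not tested. A filter or an omission also changes the number of genes or libraries.

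For slc2a12 the log2 fold change lay between -0.68 and -0.53 and passed with library weights alone (-0.61, adjusted p = 0.0467 in limma). With a correlation estimated from the data 0 lists were called, and 0 by fry, whose mixed test, open to changes in either direction, called 17. Those 17 were not the lists called by camera. They shared with these only lens, cartilage, glycolysis, skeletal muscle, skin and glia. Ribosomal proteins (mixed fry adjusted p = 0.123) and oxidative phosphorylation (mixed fry adjusted p = 0.120) did not pass. The rest were lists that camera did not call. Under the block 16 lists were called. Same-numbered libraries had correlated deviations of 0.10, -0.06 and 0.12, so the numbers were not taken to pair the pools, and not every library correlated best with its own number. Of 1575 values of named genes under the alternatives, 1486 kept direction and side of the threshold, 39 lost and 46 gained a call, and 4 changed sign. Those 4 were hk2 with equal library totals (0.063) and without control 1 (0.012) or morphant 3 (0.061), in a range of -0.16 to 0.061 with 1 library left out, and cdkn1a without control 3 (-0.046), in a range of -0.046 to 0.23. None of the 4 passed. Of 288 values of the called lists 261 were unchanged in this sense, 26 lost the call and 1 changed sign, exocrine pancreas without morphant 1 (0.0088), in a range of -0.86 to 0.0088 with 1 library left out. The cause was not tested. The planned count models were not run, because the values are not raw reads. Voom was run on reads estimated from them. Depth limits low genes most in control 1, at an estimated 7550000 reads.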

Other observations

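Some members of lists that camera did not call passed adjusted over the list alone, and most of these counts changed with 1 library left out (given in the order of controls 1, 2 and 3 and morphants 1, 2 and 3). In the inflammation and acute phase list (camera adjusted p = 0.063) 3 genes were lower (1, 1, 4, 2, 1 and 1) and 1 higher (0, 0, 1, 1, 0 and 0) adjusted over the list alone and 0 over all genes. Lower were lect2l (339 ± 56.0 in controls and 167 ± 8.39 in morphants, SD, n = 3 per group), the prostaglandin synthase gene ptgs2a (225 ± 17.0 and 163 ± 14.98) and the cytokine signalling inhibitor gene socs3a (149 ± 39.2 and 86 ± 12). Higher was the NF-kappaB inhibitor gene tnfaip3 (14.7 ± 3.06 and 32 ± 6.93). Camera called this list lower without control 2 (adjusted p = 0.028), without morphant 1 (adjusted p = 0.0033) and without morphant 3 (adjusted p = 0.0469), and also with equal library totals (where its median was above 0, at 0.07), without a filter and with library weights. In the cholesterol synthesis list (camera adjusted p = 0.291) the gene of the rate-limiting enzyme, hmgcra, was the 1 gene lower adjusted over the list alone (400 ± 36.2 and 258 ± 39.0; 1, 2, 0, 1, 0 and 1 genes with 1 library left out), with 0 genes passing over all genes. Without control 2 the list was called lower (median -0.23, camera adjusted p = 0.037), while without control 1 its median turned from -0.10 to 0.08 (camera adjusted p = 0.939). In the erythroid list (camera adjusted p = 0.544) 3 genes were lower (1, 0, 2, 5, 0 and 0) and 1 higher (2, 1, 1, 1, 1 and 1) adjusted over the list alone and 0 over all genes. The embryonic globin gene hbbe3 was higher (6, 4 and 1 in controls and 45, 112 and 41 in morphants) and hbbe2 lower (1643 ± 421 and 905 ± 277), as were hbz and si:dkey-25o16.2. Globin genes can share reads between close copies. The mTOR inhibitor gene ddit4 (270 ± 55.6 and 140 ± 17.4) and pdip5 (1138 ± 84.2 and 807 ± 68.8) were the 2 genes lower adjusted over the unfolded protein response list alone (2, 2, 1, 1, 2 and 1), with 0 over all genes (camera adjusted p = 0.109, and 0.041 without control 2, when the list was called lower).

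In the liver list (camera adjusted p = 0.278) the transferrin gene tfa (12933 ± 754 and 8834 ± 698) and ces2 (4407 ± 333 and 3037 ± 305) were lower adjusted over the list alone, 2 genes (2, 0, 2, 4, 0 and 0) against 0 over all genes. The liver list was called lower without morphant 1 (camera adjusted p = 0.0467). In the intestine list (camera adjusted p = 0.315) the lipoprotein assembly gene mtp was higher adjusted over the list alone (275 ± 38.4 and 440 ± 16.5), 1 gene (1, 0, 1, 5, 0 and 0) against 0 over all genes. That list was called higher without control 1 (camera adjusted p = 0.023), without morphant 1 (camera adjusted p = 3.0e-05) and with library weights. For fatty acid oxidation and ketogenesis (camera adjusted p = 0.833) 0 members passed over all genes or adjusted over the list alone (1 lower without control 2, 1 lower and 1 higher without morphant 1), with pdk4 at 206 ± 39.4 and 323 ± 43.2. The interferon response gave a camera adjusted p of 0.833 and 0 members either way (2 higher over the list alone without morphant 1), with isg15 at 5, 6 and 2 in controls and at 7, 125 and 49 in morphants. Among the lists not yet given, camera adjusted p-values were 0.278 for notochord and floor plate (0.012 and called lower without morphant 1), 0.315 for macrophage and neutrophil, 0.399 for oxidative stress, 0.513 for pigment cells, 0.58 for neurons and synapse and 0.764 for the glucocorticoid response. They were 0.833 for each of hypoxia, heat shock and renal tubule, and 0.987 for cell cycle and for vascular endothelium. In the oxidative stress list abcc2 was higher (679 ± 44.6 and 1001 ± 154; counts of 0, 0, 0, 1, 0 and 0 with 1 library left out) and gpx1a (689 ± 61.2 and 507 ± 54.4) and sepp1a (13305 ± 1520 and 9932 ± 595) lower adjusted over the list alone (0 lower with any 1 library left out). Of the hypoxia genes ddit4 and txnipa (3387 ± 265 and 2636 ± 72.4) were lower adjusted over the list alone, 2 genes (1, 0, 2, 1, 0 and 0), with 1 higher without control 1. Of the glucocorticoid response genes ddit4 and tsc22d3 (903 ± 41.2 and 703 ± 19.7) were lower, 2 genes (2, 2, 2, 2, 0 and 3), with 3 higher without morphant 1. The notochord list had 1 lower gene, epyc (3987 ± 184 and 2857 ± 288; counts of 1, 0, 1, 4, 0 and 0), and the macrophage and neutrophil list 1, lect2l, with a count of 1 whichever library was left out. In each of these 5 lists 0 genes passed over all genes. The lists of pigment cells, neurons and synapse, heat shock, renal tubule, cell cycle and vascular endothelium had 0 members either way, apart from 1 higher neuronal gene without control 1 and 1 higher and 1 lower without control 3.

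The tests below address patterns already seen, so none of them was fixed before the data were examined. Those that left out control 1 and that of the time of collection were also chosen after the results they measure were seen. The first pattern is the 13 lists called lower. Without control 1 camera still called 11 of the 13 lists lower, the exceptions being exocrine pancreas and hatching gland. All 13 medians stayed negative, and all moved towards 0. These 11 calls thus did not need control 1. Camera also called 6 to 21 lists when the 6 libraries were grouped 3 and 3 in other ways. All of those groupings include control 1, so they do not show how readily camera calls lists without it. How much weight a kept call carries stays open. Abundant genes were mostly lower: of 243 genes with a mean of 5000 or more, 91.4% had a negative log2 fold change, with a median of -0.24. Members of the called lists, such as rps2 and col1a1a, are among these genes. Against 10000 random lists matched on mean value, 9 of the 13 medians lay below the 2.5th percentile, while skeletal muscle, mitochondrially encoded genes, glycolysis and hatching gland did not. Skeletal muscle (median -0.205) and mitochondrially encoded genes (-0.211) fell no further than their random lists, at -0.217 and -0.314. Glycolysis was at -0.189 against -0.124. For hatching gland the random lists had a median of 0.04, so its place does not speak for a shift of abundant genes. Members of called lists could also be drawn into the random lists. The shift of abundant genes may thus come partly from the called lists, and the test cannot tell how much of the pattern it accounts for. Over 15942 genes, control 1 minus control 2 correlated with morphants minus control 3 at r = -0.364. With controls 2 and 3 swapped it was r = -0.455, where genes are not independent replicates. Removing the trend on the difference that sets control 1 apart from the comparison of morphants with 1 other control took the lists called lower from 7 to 5 with control 3 and from 9 to 6 with control 2. Those called in both comparisons went from 6 to 3 (skeletal muscle, lens and cartilage). Each comparison rests on 1 control library, so its calls reflect the spread over genes and not the spread between libraries. Oxidative phosphorylation lost its call in both as its median moved towards 0, from -0.10 (SD over members 0.16) to -0.02 (SD 0.15) with control 3 and from -0.12 (SD 0.12) to -0.04 (SD 0.12) with control 2. Ribosomal proteins lost theirs with control 3 (-0.10 before and -0.04 after) and glycolysis with control 2 (-0.13 and -0.06), while photoreceptor genes lost theirs with control 2 at an unmoved median (-0.17 before and after), which does not speak for that difference. The 6 and 4 lists that were not called with 1 control before the correction were not tested by it, and a part of that difference in the pattern stays open.

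In the 10 splits of the 6 libraries into 3 and 3, 5, the real one included, called at least as many lists as the real one. The real split called 16 lists and the highest other 21, and 10 splits are too few for a share under 0.05. A difference between clutches or in developmental pace of the pools stays open and was not tested. The second pattern is the 6 genes that rose. Without control 1 their lowest log2 fold change was 1.25, and 2 of the 6 kept their calls. Genes called with all 6 libraries have controls close together against the size of the change. Leaving out 1 control could hardly move such changes, so this test cannot decide on control 1 alone. A candidate explanation is a genetic difference between the embryos pooled in the groups: 97 genes with a log2 change of at least 2, separated groups and a mean of at least 10 (84 higher, 13 lower) spread over the chromosomes as all tested genes did (permutation p = 0.443). That result cannot exclude parents that differ across the whole genome, so parentage, an off-target effect of the morpholino and the knockdown itself cannot be told apart here. The real split called 6 genes and the highest other split 0; 1 of the 10 splits, the real one, called as many, and 10 splits are too few for a share under 0.05.

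The third pattern is the circadian clock list called higher. Collection of the pools at different times of day may raise per3, whose level cycles. Genes of the activator arm and the period and nr1d genes peak at opposite times and would then be expected to move apart, but the 5 activator genes had a median log2 fold change of 0.44 (SD 0.51) and the 7 period and nr1d genes one of 0.07 (SD 0.82). Both medians lie within the spread of their members, so time of collection and the knockdown cannot be told apart.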
